A study of Mus musculus with 49 samples.

How the data were processed

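RNA of mouse ES-D3 embryonic stem cells, an established line, was measured by sequencing while the cells were driven toward neural fates in the neural embryonic stem cell test, an in vitro assay for developmental neurotoxicity. Cells formed embryoid bodies for 3 days. They were then exposed to the antidepressants fluoxetine at 2 µM or venlafaxine at 90 µM from day 3 to day 7 or day 13. Controls, called untreated below, received neither drug, and whether they received a solvent is not given. PolyA RNA was made into strand-specific Illumina TruSeq libraries. The table held 49 libraries in 7 groups of 7: controls on days 0, 7 and 13, and each drug on days 7 and 13. The labels describe 8 samples per condition, and why 7 of each were present is not given in the sources used here. The labels name no solvent and no culture or sequencing batch, and do not say whether the 7 samples of a group came from separate differentiations, so every p-value measures the spread between samples whose independence is not stated.

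The deposited values were raw counts per gene, 1 column per library, and no normalized unit was used. Per the submitters' processing notes, the authors used bcl2fastq 2.19.0.316, FastQC 0.11.5, STAR 2.6.0b and featureCounts 1.6.1 with mouse build GRCm38.p6. The annotation release, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Counts of genes that overlap a neighbour (such as Hoxc4 and Hoxc5) or have close paralogs (such as Hspa1a and Gbp8) may therefore hold reads of another gene. The table had 52550 gene rows. In 26 of these the symbol had been turned into a date by a spreadsheet and was restored. In all, 52403 rows matched an identifier of the GENCODE vM21 annotation of GRCm38, from which coordinates, GC content and transcript lengths were taken. For 90 rows that shared a symbol with a row of higher count, the row of higher count carried the name. No 2 libraries were copies of each other.

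Totals ran from 14059811 to 29225775 counts per library. On counts simulated from the measured control means and spread, with 7 against 7 libraries, edgeR recovered 20 to 26 of 50 genes changed 1.2-fold, 35 to 44 of 50 changed 1.5-fold, 46 to 50 of 50 changed 2-fold and 50 of 50 changed 4-fold in the 4 comparisons of a drug with its control, with 1 to 9 false calls. The simulation drew each gene independently and changed only genes with a control mean of at least 1 CPM. It left out variation shared between genes, so these figures do not give the level of false calls in the measured libraries.

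Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, robust quasi-likelihood F test) and called at a Benjamini-Hochberg adjusted p under 0.05. The 3 groups of a day were fitted together for the drug comparisons, the 3 control groups for the time course, and the 42 libraries of days 7 and 13 for the difference between a drug's effects on the 2 days. Errors of log2 fold changes are the fold change divided by the root of F. CPM values were computed here from the counts and TMM factors, with a prior count of 2 on the log2 scale. A second question was how far a drug moved expression along the untreated course. Each library was given a position by projection on the untreated change from day 7 to day 13, with a control left out of that change for its own position. For correlations of a drug effect with this change, controls were also split so that no control entered both sides. Since both drugs shared the 7 controls of a day, their effects were also compared in 20 simulations with unchanged groups and in 35 splits of the controls into 4 and 3.

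A set of 38 gene lists (598 entries) for neural and other cell types, regional identity, metabolism and stress was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 37 lists with enough counted genes in each comparison. Beside it stand camera with an estimated correlation, the number of members called over all genes, and the number adjusted over the list alone. Genes named in the text are the 8 with the highest and the 8 with the lowest log2 fold change in each comparison of a drug with its control (5 and 5 in the other comparisons), among called genes with a proper symbol, a mean of at least 2 CPM in the higher group and at least 6 of 7 libraries on the called side of the median of the other group; up to 4 members of a list with the smallest p, and members needed to describe what did not move; and a panel of Slc6a4, Slc6a2, Pou5f1, Nanog, Nes, Pax6, Tubb3, Map2, Gfap, S100b, Olig2 and Mbp. In the time course and day comparisons the text names a part of these, and a few genes that the rule takes are not reported here. Lists, tests, the naming rule and the first set of alternatives were fixed before the data were examined. Those alternatives were DESeq2 size factors in edgeR, no count filter, a filter of 1 CPM in 7 libraries, DESeq2 1.42.0, limma voom with sample weights, other sets of libraries in the fit, and the replicate number as a block. Chosen after seeing the data were an exact permutation test (2-sided) of the mean log2 CPM of a list per library over all 3432 assignments, a permutation of residuals for differences between days, a correction for GC content and length in each library, and fits without the library farthest from its group mean in all groups at once. A count of genes called in random splits of the same libraries accompanies each comparison. Figures were drawn with matplotlib 3.10.9. No library and no column was left out.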

Results

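Gene expression was measured by RNA sequencing in 49 cultures of differentiating mouse embryonic stem cells, 7 in each of 7 groups. Libraries held 18567890 ± 3412268 counts on day 0 (mean ± SD, n = 7), 20332563 ± 4516293 in day 7 controls and 22037247 ± 4676386 in day 13 controls. The fluoxetine groups held 19659949 ± 3278444 counts on day 7 and 20615334 ± 4639739 on day 13. The venlafaxine groups held 17193641 ± 2760895 and 21118728 ± 4685856. Mitochondrial transcripts took 1.91% of counts on day 0, and group means of 1.4% to 1.72% on days 7 and 13. Log2 fold changes are given with their standard errors, n is 7 per group throughout, and p-values of genes and lists are adjusted.

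The untreated time course gave the background against which both drugs were read. Between day 0 and day 7 pluripotency genes fell and neural progenitor genes rose. All 21 measured pluripotency genes fell, among them Esrrb, a regulator of the naive state, from 826 to 8.93 CPM (log2 fold change -6.51 ± 0.109). Of 16 neural progenitor genes 14 rose and 2 fell. Those that rose included the RNA-binding protein gene Msi1 (4.05 ± 0.0548) and Pax6, which went from 1.92 to 171 CPM. All 12 neurogenic factors rose, including Insm1 (5.41 ± 0.124) and the Notch ligand gene Dll1 (5.73 ± 0.112). Of 22 Hox genes, which pattern the hindbrain and spinal cord, 21 rose, with Hoxb4 at 6.74 ± 0.133. Of 11 oxidative stress genes 10 fell, and of 25 sterol genes 22 rose (Hmgcs1 at 1.82 ± 0.0589).

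From day 7 to day 13 genes of neurons and glia rose and genes of proliferation fell. Of 25 general neuron genes 23 rose, such as Mapt, which codes for tau (40.1 to 1183 CPM, 4.88 ± 0.0722), and the synaptic vesicle gene Syn1 (3.63 ± 0.0664). The glutamate receptor gene Grin2b (6.81 ± 0.157) and the astrocyte gene Aldh1l1 (1.67 to 55.4 CPM) rose as well. So did 10 of 12 glutamatergic, 8 of 11 GABAergic, 12 of 16 astrocyte and 15 of 17 oligodendrocyte lineage genes. All 22 cell cycle genes fell, with Top2a at -2.18 ± 0.092. So did 11 of 12 endoderm genes (Gata6 at -2.51 ± 0.0713), 15 of 17 genes of the integrated stress response and 11 of 13 epithelial genes. Slc6a4, the serotonin transporter and the target of both drugs, rose from 0.532 to 12.8 CPM (4.59 ± 0.325). Called genes numbered 15060 of 16969 for day 7 against day 0 (7695 higher) and 14090 for day 13 against day 7 (7143 higher). Camera called 7 and 9 lists, and all lost their call with an estimated correlation, where the smallest adjusted p was 0.141 and 0.204. The exact permutation test called 35 and 30 of the 37 lists, at smallest adjusted p of 0.000674 and 0.00098. An unadjusted p of 0.000583 is the smallest it can give.

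Whether 2 µM fluoxetine changed expression by day 7, after 4 days of exposure, was asked against day 7 controls. Only small changes passed the test, and lysosomal genes stood out. Uap1l1 (0.39 ± 0.0578; 32.9 ± 2.45 against 25.1 ± 2.02 CPM; chromosome 2, 25359889 to 25365682, minus strand of GRCm38) rose with its neighbour Dpp7, a lysosomal peptidase gene (0.31 ± 0.0512; chromosome 2, 25352276 to 25356359). Also higher were Impact (0.26 ± 0.0439), Mfsd1 (0.18 ± 0.0309), a lysosomal transporter gene, and Atp6ap2 (0.18 ± 0.0316), a gene of the proton pump that acidifies lysosomes. Rnf145, a ubiquitin ligase gene linked to sterol control (-0.27 ± 0.0282, adjusted p = 8.76e-06), Klf8 (-0.24 ± 0.0451) and Snn (-0.18 ± 0.0322) fell. Each of these 8 genes lay on its side of the control median in 7 of 7 libraries.

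Of the 23 lysosome genes in the list none passed over all genes, and 11 were higher adjusted over the list alone, with Lamp1 at 0.16 ± 0.0362 (adjusted p = 0.118). The list as a whole was higher in fluoxetine than in control, with a median log2 fold change of 0.11. Its score was 6.71 ± 0.04 against 6.6 ± 0.039, above the control median in 7 of 7 libraries (camera adjusted p = 1.26e-13, p = 0.0113 with an estimated correlation, exact p = 0.0216). For the 22 cell cycle genes the median was -0.06 (camera p = 8.28e-05, exact p = 0.0216), but adjusted p = 0.208 with an estimated correlation, and 2 members were lower adjusted over the list alone. Sterol genes (25, median 0.13, 5 higher over the list alone) had a camera p of 3.91e-10, p = 0.442 with an estimated correlation and exact p = 0.313. Among neurogenic factors 3 of 12 were higher adjusted over the list alone, with Neurod4 at 0.42 ± 0.0858 (adjusted p = 0.0664). Camera called 13 lists in all, of which the lysosome list alone held with an estimated correlation, and lysosome and cell cycle in the exact test. Among the others pluripotency genes lay above 0 in 20 of 21 cases (median 0.28; camera p = 0.00294, p = 0.744 with an estimated correlation) and neural progenitor genes below it in 14 of 16 (median -0.126; camera p = 0.000115, p = 0.442 with an estimated correlation). None of the 10 counted panel genes was called. Slc6a4 was at 0.639 CPM against 0.57, and Nes at -0.11 ± 0.046 (adjusted p = 0.479).

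In all, 8 of 15601 genes were called (5 higher, 3 lower), all changed less than 1.5-fold, while 1424 had an unadjusted p under 0.05. The count was 57 with DESeq2, 53 with voom, 15 after the GC and length correction, 14 in a fit of the 2 groups alone, and 18 in a fit of all 49 libraries. It was 5 without con_d7_5, flx_d7_2 and vnx_d7_5, where Mfsd1, Atp6ap2, Klf8 and Snn lost their call. With no filter 6 genes were called, and 6 with the replicate number as a block, and each held 4 of the 8. Of the 8, 5 kept their call in the fit of all 49 libraries and 6 in that of the 2 groups.

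Venlafaxine at 90 µM, exposed for the same time, changed 599 genes on day 7, among them lysosomal, sterol, glycolytic and neurogenic genes. The midbrain and hindbrain gene En2 rose most among the genes named (1.17 ± 0.236; 6.32 ± 1.69 against 2.75 ± 0.848 CPM; chromosome 5, 28165694 to 28172166). It was followed by S100a1 (0.86 ± 0.127), Tfec (0.78 ± 0.176), a relative of the lysosomal regulator TFEB, Nupr1 (0.75 ± 0.195), Spry4 (0.66 ± 0.148), the radial glia gene Fabp7 (0.64 ± 0.13), Uap1l1 (0.64 ± 0.0578) and Gbp8 (0.63 ± 0.146). Igfbp1, which binds insulin-like growth factors, had the largest fall (log2 fold change -1.80 ± 0.181, 4.57 ± 1.31 against 15.9 ± 3.52 CPM; chromosome 11, 7197782 to 7202546). Hspa1a (-1.23 ± 0.192), Aifm3 (-1.17 ± 0.145), Gpx2 (-1.06 ± 0.16), Serpina10 (-1.03 ± 0.173), Stc1 (-0.96 ± 0.248) and Irf4 (-0.92 ± 0.113) also fell, from control means of 2.11 to 9.94 CPM. Th, the rate-limiting enzyme of catecholamine synthesis, fell from 2.31 ± 0.484 to 1.17 ± 0.328 CPM.

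Of 23 lysosome genes 14 rose and 0 fell (19 higher adjusted over the list alone), such as Hexa (0.38 ± 0.0412), Lamp1 (0.32 ± 0.0363) and Ctsa (0.30 ± 0.0348). The list median was 0.21, with camera p = 1.96e-31, p = 7.94e-05 with an estimated correlation and exact p = 0.0108. Of 25 sterol genes 12 rose (18 over the list alone), such as Cyp51, a demethylase of cholesterol synthesis (0.49 ± 0.0561; 305 against 218 CPM), and Nsdhl (0.30 ± 0.0532). Of 12 fatty acid genes 5 rose, such as Srebf1 (0.24 ± 0.0508). Of 16 hypoxia and glycolysis genes 8 fell (14 over the list alone), such as Aldoa (-0.33 ± 0.0603), Pdk1 (-0.41 ± 0.097) and Hk2 (-0.28 ± 0.068). Of 12 neurogenic factors 6 rose, among them Insm1 (0.48 ± 0.0759), Neurod4 (0.48 ± 0.0861) and Neurog1 (0.39 ± 0.0673). The sterol, fatty acid, hypoxia and neurogenic lists had camera p from 4.26e-07 to 3.39e-21. In that order their exact p was 0.0216, 0.0277, 0.0277 and 0.0108, but adjusted p = 0.0734, 0.126, 0.0866 and 0.0734 with an estimated correlation.

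Smaller movements were seen in cell cycle genes, of which 2 of 22 fell (Aurkb at -0.21 ± 0.0499, Mcm6 at -0.17 ± 0.0388; camera p = 0.000196, exact p = 0.0269, p = 0.126 with an estimated correlation). Of 14 astrocyte genes 3 fell (Ndrg2 at -0.66 ± 0.0976; camera p = 0.0486, 0.19 without the farthest libraries con_d7_5, flx_d7_2 and vnx_d7_5; exact p = 0.0703, p = 0.126 with an estimated correlation). The endothelial receptor gene Flt1 (-0.59 ± 0.0675) and the oligodendrocyte precursor and mesenchymal gene Pdgfra (-0.34 ± 0.072) fell. The pluripotency list had a median of 0.57 with 0 of its members called (camera p = 2.77e-05, p = 0.63 with an estimated correlation, exact p = 0.282), and one of 0.203 without con_d7_5, flx_d7_2 and vnx_d7_5 (camera p = 0.037). Pou5f1 was at 0.92 (adjusted p = 0.156), with 41.3 CPM in vnx_d7_5 and 7.49 to 19.4 in the other 6 venlafaxine libraries. None of the 10 counted panel genes was called, and Slc6a4 stood at 0.589 CPM against 0.57.

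Called genes numbered 599 of 15601 (296 higher, 303 lower), of which 75 changed over 1.5-fold (22 higher, 53 lower). Without con_d7_5, flx_d7_2 and vnx_d7_5 the genes Nupr1, Stc1, Pdk1, Hk2, Aurkb, Slc1a3 and Aldoc lost their call. The count was 290 with the replicate number as a block.

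**Figure D1:**
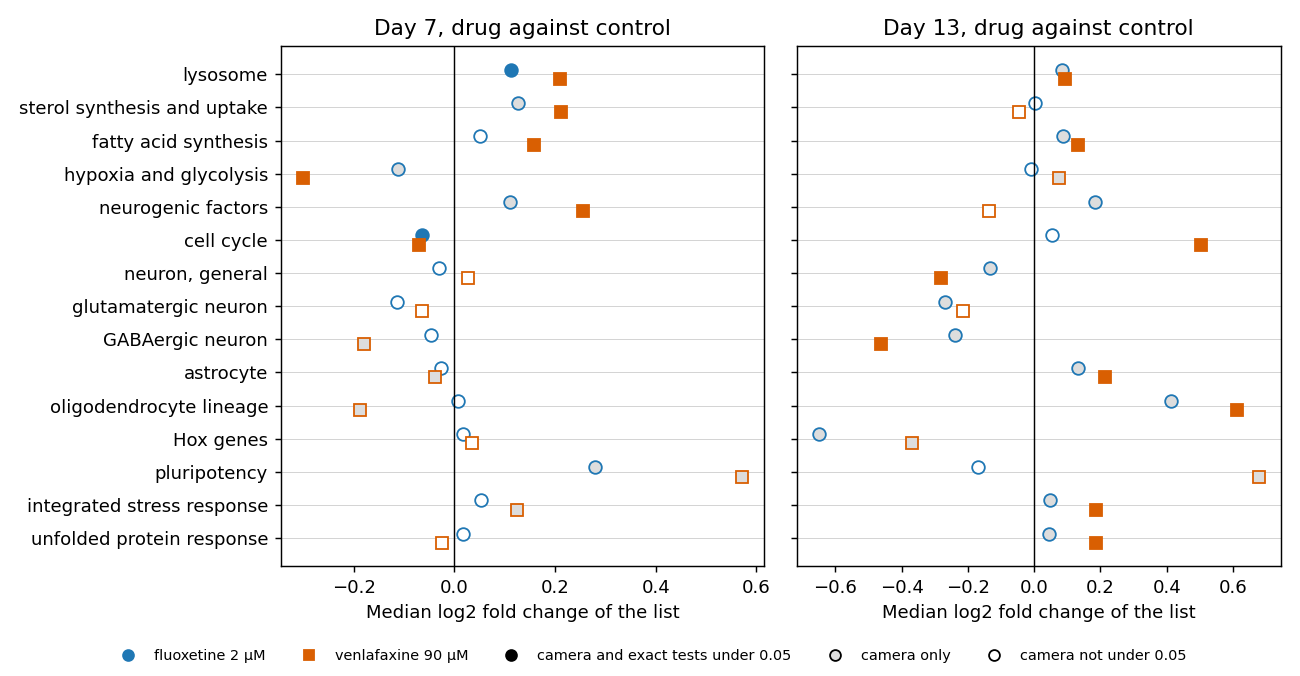
Median log2 fold change (x axis) of 15 gene lists (y axis) in fluoxetine (circles) and venlafaxine (squares) against control on day 7 and day 13. Filled symbols had camera and exact adjusted p under 0.05, grey symbols camera alone, and open symbols no camera call; lysosome medians on day 7 were 0.113 for fluoxetine and 0.209 for venlafaxine.

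**Figure D2:**
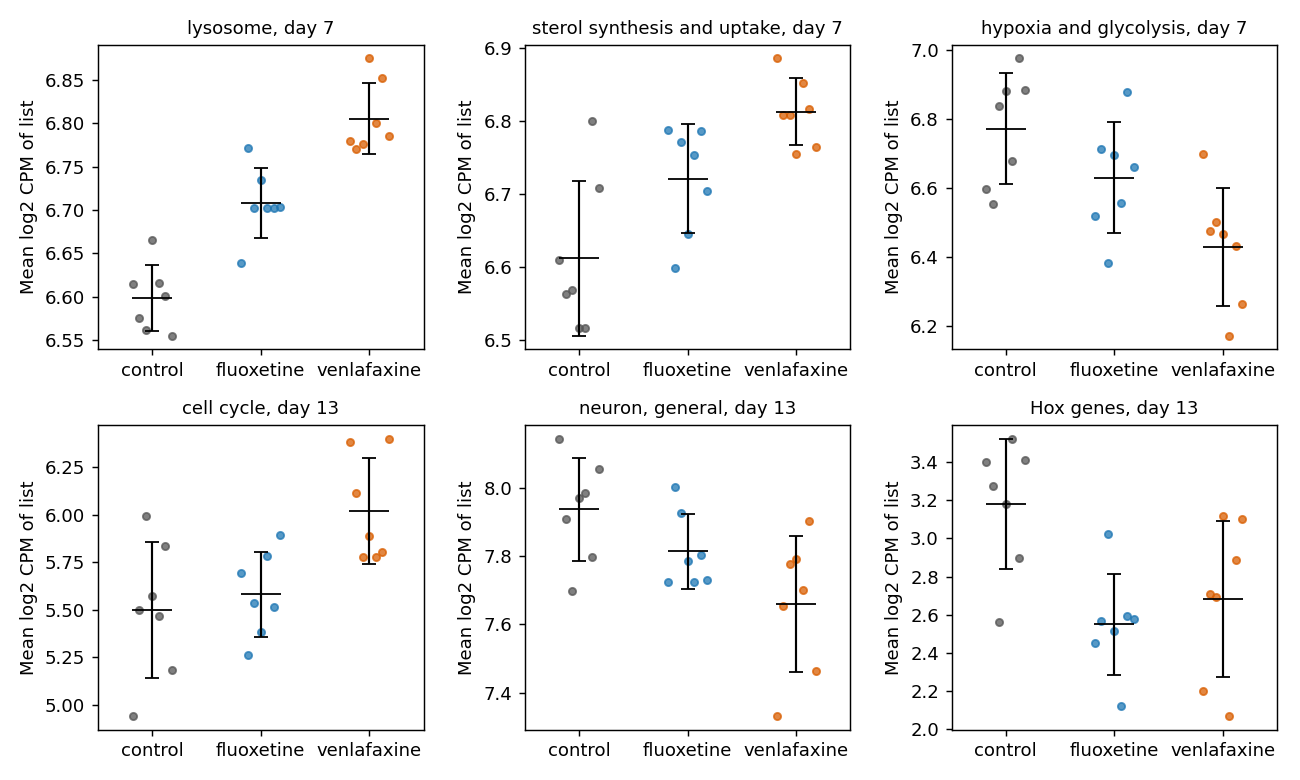
List score (mean log2 CPM of the genes of a list, y axis) in each library of the control, fluoxetine and venlafaxine groups, with the group mean and SD (n = 7), for 3 lists on day 7 and 3 on day 13. On day 7 the lysosome score lay above the control median in 7 of 7 libraries of either drug.

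Set against each other at these unequal doses, the drugs differed in few genes on day 7. Igfbp1 (1.29 ± 0.184; 11.3 against 4.57 CPM), Th (0.91 ± 0.172), Stra6l (0.82 ± 0.169), Aifm3 (0.72 ± 0.148) and Vsig2 (0.68 ± 0.119) were higher in fluoxetine. Cdh10 (-0.36 ± 0.0769), the lysosomal genes Ctsh (-0.32 ± 0.0666), Hexa (-0.30 ± 0.0411), Ctns (-0.21 ± 0.0337) and Ctsa (-0.18 ± 0.0347) and the inhibitor of differentiation gene Id2 (-0.22 ± 0.0424) were higher in venlafaxine. The lysosome list was lower in fluoxetine than in venlafaxine (median -0.09, 2 of 23 called and 10 over the list alone; camera p = 1.05e-13, p = 0.0103 with an estimated correlation, exact p = 0.0216). The hypoxia list had a median of 0.19 (camera p = 1.81e-11, p = 0.146 with an estimated correlation, exact p = 0.237). The monoaminergic list, in which Th alone was called, had one of 0.19 (camera p = 0.00225, p = 0.101 with an estimated correlation, exact p = 0.0216), and of 0.111 without con_d7_5, flx_d7_2 and vnx_d7_5. In all 23 genes were called, 16 higher and 7 lower in fluoxetine. The count was 112 with DESeq2, 56 after the GC and length correction, 49 with voom, and 8 in a fit of the 2 groups alone. It was 14 without con_d7_5, flx_d7_2 and vnx_d7_5, where Th, Stra6l, Aifm3, Cdh10, Id2 and Ctsa lost their call.

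Both drugs were compared with the same 7 controls, which alone makes their effects correlate. Across genes, which are not independent replicates, the day 7 effects correlated at r = 0.592 (0.486 in simulations of unchanged groups) and at 0.201 (0.0528 to 0.318) with split controls. The covariance was 0.0129 against 0.00725 in the simulations. Over all genes 73.5% had the same sign in both (66.3% in the simulations). For both drugs 5 genes were called higher and 2 lower, where independent calls would give 0.0949 and 0.0583, a figure that makes no allowance for the shared controls. On day 13 the correlation was 0.385 (simulated 0.493) and 0.18 (-0.0214 to 0.258) with split controls, and the covariance 0.0215 against 0.0105 in the simulations. The same sign was seen in 66.3% of genes (66.6% simulated), and 5 were called higher and 2 lower for both, against 1.16 and 1.02 for independent calls.

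By day 13, after 10 days, 19 genes differed between fluoxetine and control cultures, among them the transcription factor gene Nkx6-1, which was higher, and the neuropeptide gene Tac1, which was lower. Nkx6-1 (0.71 ± 0.122; 116 ± 21.5 against 70.5 ± 11.3 CPM; chromosome 5, 101658139 to 101664996) and Lhx4 (0.45 ± 0.0836), which act in motor neuron and interneuron specification, rose. So did the astrocyte enzyme gene Aldh1l1 (0.58 ± 0.114), Mecom (0.51 ± 0.0994), Ntng2 (0.48 ± 0.0956), the endothelin receptor gene Ednrb (0.40 ± 0.0727), Ephb1 (0.30 ± 0.0589) and Pou3f3 (0.21 ± 0.0375). Tac1, the precursor of substance P, had the largest fall (log2 fold change -1.89 ± 0.338; 0.85 ± 0.371 against 3.14 ± 0.752 CPM; chromosome 6, 7554879 to 7565834). It was followed by Rasgrf2 (-0.78 ± 0.152), the potassium channel gene Kcnh1 (-0.72 ± 0.141), Plekhd1 (-0.57 ± 0.113), Zmat4 (-0.48 ± 0.0922), Sphkap (-0.45 ± 0.0888), Fam49a (-0.31 ± 0.0584) and Magi3 (-0.27 ± 0.052). All had adjusted p from 0.0461 to 0.0491 and lay on their side of the control median in 7 of 7 libraries.

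Camera called 18 lists in this comparison, but none held with an estimated correlation or in the exact test. The 21 Hox genes had a median of -0.65 (12 lower adjusted over the list alone; camera p = 2.52e-08, p = 0.248 with an estimated correlation, exact p = 0.0752; 0 of 7 libraries above the control median). Hoxb5 was at -1.34 ± 0.304 (adjusted p = 0.0604) and Hoxb8 at -1.20 ± 0.338. The libraries flx_d13_5, flx_d13_6 and flx_d13_7 had the lowest Hoxb8 of their group (5.56 to 9.21 CPM) and lay apart from the other day 13 libraries on the second principal component (19.09 to 38.49, the others at most 11.41). Their Hox scores overlapped with those of the other 4 fluoxetine libraries. They also had the highest Nkx6-1 of their group (121 to 146 CPM). The other 4 were at 88.8 to 112 and controls at 58.5 to 85.6. The 17 oligodendrocyte lineage genes had a median of 0.41 (camera p = 6.32e-08, p = 0.334 with an estimated correlation, exact p = 0.213). The 12 glutamatergic genes had one of -0.27 (camera p = 3.34e-05, p = 0.248 with an estimated correlation, exact p = 0.0752), with Slc17a6 at -0.69 ± 0.175 and Neurod6 at -0.78 ± 0.198. Of 17 astrocyte genes Aldh1l1 alone was called, and of 9 cholinergic and motor neuron genes Lhx4 alone. The lysosome list was at 0.08 (4 higher over the list alone; exact p = 0.0752) and fatty acid synthesis at 0.09 (5 over the list alone; exact p = 0.0752). No panel gene was called. Slc6a4 stood at 26.1 ± 11.3 against 13.5 ± 5.98 CPM (0.95 ± 0.309, adjusted p = 0.146) and Gfap at -0.90 ± 0.222 (adjusted p = 0.0682).

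Of 16397 genes 19 were called (10 higher, 9 lower; 4 over 1.5-fold), with 2312 at an unadjusted p under 0.05. This count depended on the tool and was 423 with DESeq2 and 454 with voom (all 19 included in both), 575 in a fit of all 49 libraries, 45 with a filter of 1 CPM, 36 after the GC and length correction, and 29 with no filter. It was 58 without con_d13_4, flx_d13_5 and vnx_d13_1, where Mecom, Ntng2 and Fam49a lost their call. With the replicate number as a block it was 0, and none of the 19 kept its call, although these numbers did not pair the libraries. Of the 19, 11 kept their call in a fit of the 2 groups alone (17 called) and 16 with no filter.

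Venlafaxine cultures on day 13 had higher cell cycle and glial genes and lower neuronal genes than control cultures. On the first principal component of the day 13 libraries (36.9% of variance) the groups overlapped. Venlafaxine libraries lay at 8.25 to 45.07 and controls at -44.67 to 24.02, with con_d13_4 the highest control. Untreated cultures thus varied along the same component, and how much of the difference this variation holds was not tested. Cell cycle genes rose in 19 of 22 cases, such as Mki67 (0.49 ± 0.118; 247 ± 33.8 against 176 ± 37.9 CPM; chromosome 7, 135689784 to 135716361), Plk1 (0.58 ± 0.129) and Birc5 (0.51 ± 0.132), with a list median of 0.50. Of 25 general neuron genes 19 fell, such as Stmn2 (-0.38 ± 0.0841; 468 ± 55.8 against 609 ± 77 CPM), Nefl (-0.39 ± 0.0874), Gap43 (-0.27 ± 0.0611) and Tubb3 (-0.22 ± 0.0741). Of 11 GABAergic genes 7 fell, such as Gad1 (-0.46 ± 0.143) and Sst (-0.72 ± 0.184), and of 12 glutamatergic genes Neurod6 (-0.77 ± 0.198) and Neurod2 (-0.73 ± 0.19). Of 17 oligodendrocyte lineage genes 12 rose, among them Mbp, a myelin protein gene (0.79 ± 0.211; 177 ± 53.3 against 102 ± 40.9 CPM), Myrf (0.91 ± 0.206) and Bcas1 (0.83 ± 0.187). Of 17 astrocyte genes 8 rose, such as Aldh1l1 (0.70 ± 0.114), Glul (0.37 ± 0.0627) and S100b (1.04 ± 0.238), while Gfap fell (-0.78 ± 0.22).

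Among called genes with a mean of at least 2 CPM in the higher group and at least 6 of 7 libraries on their side of the other group's median, those with the largest rises were Foxd4 (2.14 ± 0.488), the ion channel gene Trpv3 (1.93 ± 0.152), Vrtn (1.85 ± 0.531), Clps (1.81 ± 0.194), the stem cell gene Eras (1.73 ± 0.436), the mesoderm gene T (1.70 ± 0.455; 24.9 ± 7.66 against 7.59 ± 5.33 CPM; chromosome 17, 8434423 to 8442496), Phlda2 (1.70 ± 0.49) and Prl2b1 (1.54 ± 0.331). Within the same limits the largest falls were those of Tlx1 (-1.42 ± 0.428), Phox2a (-1.15 ± 0.345), Aifm3 (-1.12 ± 0.179), Npy (-1.12 ± 0.385), Aqp6 (-1.10 ± 0.346), Pax8 (-1.01 ± 0.293), Hoxc4 (-0.99 ± 0.199) and Serpina3n (-0.94 ± 0.148). Of 21 Hox genes 7 fell, such as Hoxb4 (-0.47 ± 0.0905) and, at means under 2 CPM, Hoxc5 (-1.27 ± 0.281), while 3 of 6 forebrain genes, at means under 2 CPM, rose, such as Hesx1 (1.97 ± 0.507) and Six3 (1.64 ± 0.422), with 3 of 9 early mesoderm genes. Of 21 pluripotency genes 3 rose, such as Dnmt3l (1.47 ± 0.373), and Pou5f1 was at 1.05 ± 0.437 (adjusted p = 0.0831). Over all genes 22.9% were called in this comparison.

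Members of other lists were called as well, in a comparison where 22.9% of all genes were called, 1897 higher and 1856 lower. Counts of members near this share say little about a list. Of 17 genes of the integrated stress response 10 rose (Trib3 at 0.55 ± 0.118, Atf3 at 0.53 ± 0.096), with 7 of 13 of the unfolded protein response (Hspa5 at 0.21 ± 0.0578) and 4 of 11 of the oxidative stress list (Hmox1 at 0.66 ± 0.125). Rises were also seen in 6 of 12 fatty acid genes (Scd1 at 0.44 ± 0.0954), 5 of 15 hypoxia genes (Slc2a1 at 0.59 ± 0.103, Ndrg1 at 0.65 ± 0.0777), 5 of 12 choroid plexus genes (Otx2 at 1.33 ± 0.401), 4 of 13 epithelial genes (Krt8 at 0.67 ± 0.211) and 6 of 23 lysosome genes (Hexa at 0.37 ± 0.062; 2 fell). Of 25 sterol genes 3 rose and 6 fell. A set of 39 genes abundant on day 0 and at least 50-fold lower in day 7 controls was used to follow stem cell transcripts. Their median level was 2.89 ± 0.873% of that on day 0 in venlafaxine, 1.64 ± 0.961% in control and 1.48 ± 0.732% in fluoxetine cultures (unadjusted exact p = 0.0268 for venlafaxine and 0.735 for fluoxetine against control). Slc6a4 was at 13.2 ± 5.77 against 13.5 ± 5.98 CPM (adjusted p = 0.937).

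In all 3753 of 16397 genes were called (1897 higher, 1856 lower), and 535 changed over 1.5-fold, 455 of them higher. Camera called 17 lists, from p = 1.66e-11 for cell cycle to 0.0201 for forebrain genes, and the exact test 18, with adjusted p = 0.0259 for cell cycle, neuron and oligodendrocyte genes, 0.0162 for astrocyte and 0.0215 for stress response and forebrain genes. It was 0.0583 for Hox and pluripotency genes, 0.105 for epithelial and 0.103 for hypoxia genes. No list held with an estimated correlation, where the smallest adjusted p was 0.326. The count was 2022 with no filter and 2301 in a fit of the 2 groups alone. It was 282 with the replicate number as a block, where 46 of the genes named for this comparison lost their call.

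**Figure D3:**
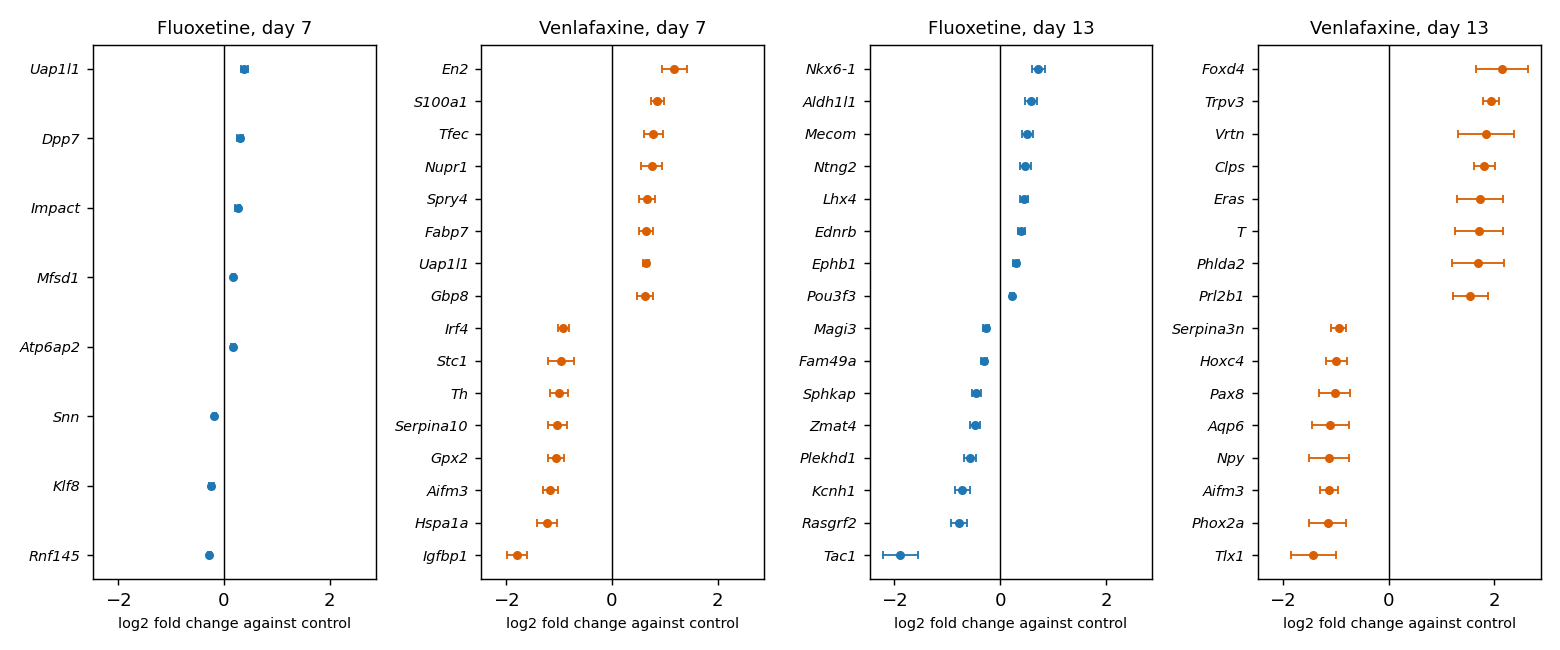
Log2 fold change against control with its standard error (x axis, n = 7 per group) of the called genes with the highest and lowest values (y axis) in each drug on each day, at most 16 per comparison, among genes with a mean of at least 2 CPM in the higher group and at least 6 of 7 libraries on the called side. Values shown ran from -1.89 (Tac1) to 0.71 (Nkx6-1) for fluoxetine on day 13 and from -1.42 (Tlx1) to 2.14 (Foxd4) for venlafaxine on day 13.

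**Figure D4:**
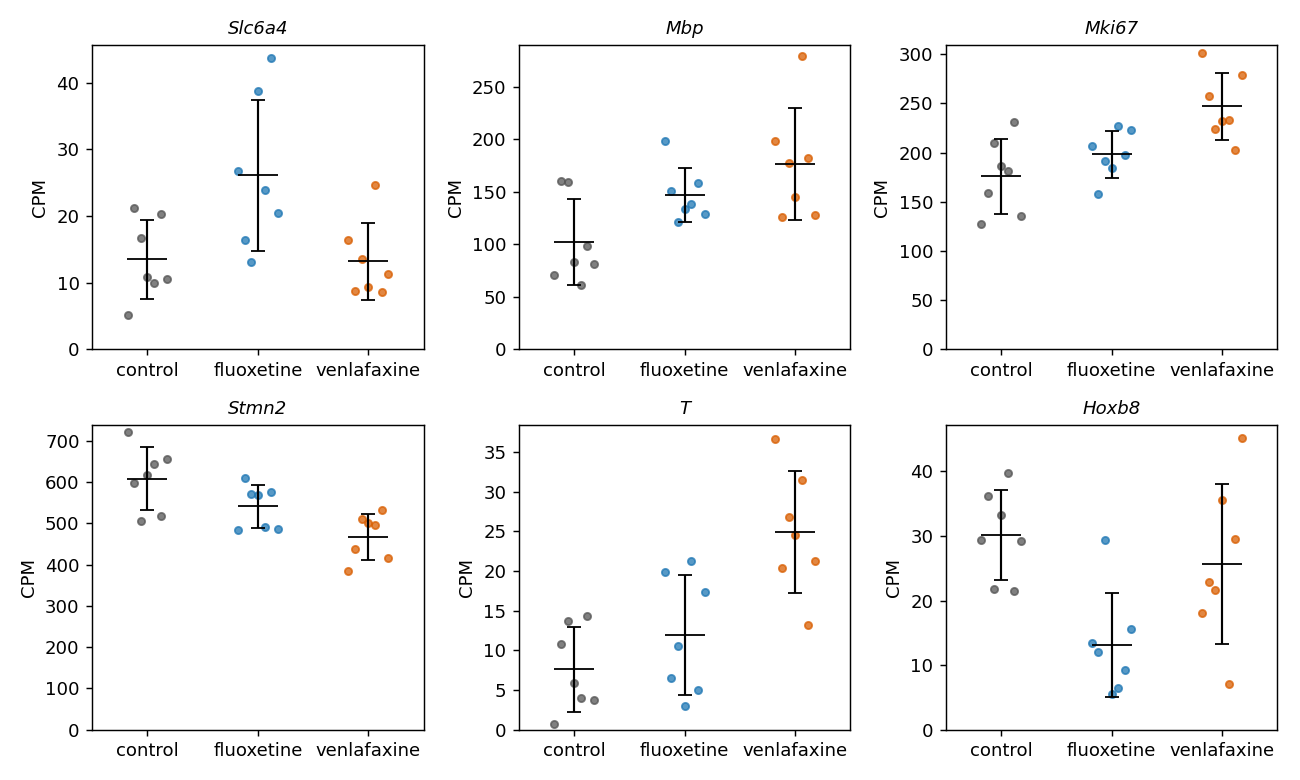
Expression (CPM, y axis) of 6 genes in each day 13 library of the control, fluoxetine and venlafaxine groups, with the group mean and SD (n = 7). Slc6a4 averaged 26.1 CPM in fluoxetine cultures and 13.5 in controls (not called), and Mki67 averaged 247 CPM in venlafaxine cultures and 176 in controls (called).

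Directly compared on day 13, fluoxetine cultures had higher levels of 4 genes of serotonergic neurons than venlafaxine cultures. They had lower levels of genes in the cell cycle, pluripotency and forebrain lists. Whether cells of forebrain identity differed between the cultures was not tested. Slc6a4 (0.99 ± 0.31; 26.1 ± 11.3 against 13.2 ± 5.77 CPM; chromosome 11, 76998603 to 77032340), the vesicular monoamine transporter gene Slc18a2 (0.98 ± 0.257), Tph2, the enzyme of neuronal serotonin synthesis (0.88 ± 0.253), and its regulator Fev (0.88 ± 0.268) were higher in fluoxetine. Each lay above the venlafaxine median in 7 of 7 fluoxetine libraries. The groups overlapped for Slc6a4, at 13.1 to 43.8 CPM in fluoxetine and 8.55 to 24.6 in venlafaxine. It was highest in flx_d13_7 and flx_d13_5 (43.8 and 38.7 CPM), which lay apart on the second principal component. The third library set apart there, flx_d13_6, was at 23.9 and flx_d13_1 at 26.7. In venlafaxine Slc6a4 was highest in vnx_d13_5, which also lay highest of its group on that component (11.41). Whether the difference is separate from this variation between cultures was not tested. The monoaminergic list as a whole was not called (4 of 15 higher, 1 lower, median 0.17; camera p = 0.172, exact p = 0.243). Actc1, a heart and skeletal muscle gene at 15 to 19.1 CPM in flx_d13_5, flx_d13_6 and flx_d13_7 and 0.103 to 2.66 in the other 4 (8.09 ± 8.73 against 0.483 ± 0.729 CPM), Foxc1 (1.29 ± 0.373), Lamc3 (1.24 ± 0.346), Tnnc1 (1.23 ± 0.345) and Insm1 (0.56 ± 0.0881) were higher in fluoxetine. Eras (-2.39 ± 0.469), Vrtn (-2.02 ± 0.544), Fgf5 (-1.93 ± 0.476), Phlda2 (-1.79 ± 0.501), the DNA methyltransferase gene Dnmt3b (-1.77 ± 0.431), Hesx1 (-2.47 ± 0.544), Six3 (-1.53 ± 0.422) and Krt18 (-0.85 ± 0.216) were higher in venlafaxine. Of 22 cell cycle genes 10 were lower in fluoxetine (22 over the list alone; median -0.44), such as Mcm5 (-0.66 ± 0.19), with 4 of 21 pluripotency and 4 of 6 forebrain genes. Exact p was 0.0345, 0.0345 and 0.0108 for the 3 lists, and adjusted p was 0.42, 0.473 and 0.385 with an estimated correlation. In all 1986 genes were called (843 higher, 1143 lower in fluoxetine). The count was 236 without con_d13_4, flx_d13_5 and vnx_d13_1, where Eras, Dnmt3b and Insm1 kept their call and the other genes named here, the serotonergic ones included, lost it. It was 889 with no filter, 176 with the replicate number as a block and 3467 in a fit of all 49 libraries.

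The effect of a drug on day 13 was tested against its effect on day 7. For fluoxetine 47 of 16964 genes differed (36 with a higher day 13 effect), such as the matrix gene Fbln2 (1.31 ± 0.304), Ednrb (0.54 ± 0.0973) and Plekhd1 (-1.09 ± 0.221). For venlafaxine 2107 differed (1277 with a higher day 13 effect). Of 22 cell cycle genes 18 had a higher effect on day 13, such as Plk1 (0.68 ± 0.132), as did 10 of 16 hypoxia genes, such as Slc2a1 (0.78 ± 0.117), and 6 of 17 oligodendrocyte genes. A lower effect was seen in 13 of 25 sterol genes, such as Cyp51 (-0.52 ± 0.0726), and 6 of 13 neurogenic factors, such as Insm1 (-0.61 ± 0.121). For fluoxetine the count was 5 with DESeq2 size factors, 4 with no filter, 181 with DESeq2, 464 with voom, and 83 in a fit of all 49 libraries. It was 5 without the farthest libraries (con_d7_5, con_d13_4, flx_d7_2, flx_d13_5, vnx_d7_5, vnx_d13_1), where Fbln2 and Plekhd1 lost their call. For venlafaxine it was 1186 with no filter.

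Along the untreated course from day 7 to day 13, venlafaxine cultures on day 13 were placed behind their controls, a difference that did not pass after adjustment. On a scale of 0 for day 7 and 1 for day 13 controls their position was 0.92 ± 0.061 against 0.993 ± 0.059, with 0 of 7 libraries above the control median (exact p = 0.0443, adjusted p = 0.177 over 4 comparisons). Across genes the venlafaxine effect on day 13 correlated with the untreated change at r = -0.403 with all controls, where simulations of unchanged groups averaged -0.0562. With split controls it was -0.351 (-0.372 to -0.283). The simulations drew genes independently and the spread of their r was not kept, so they do not show how far chance reaches. Fluoxetine cultures on day 13 were at 0.972 ± 0.037 (exact p = 0.44), and on day 7 the differences were -0.00776 for fluoxetine and 0.00236 for venlafaxine (exact p = 0.505 and 0.804). None of the 4 passed after adjustment.

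**Figure D5:**
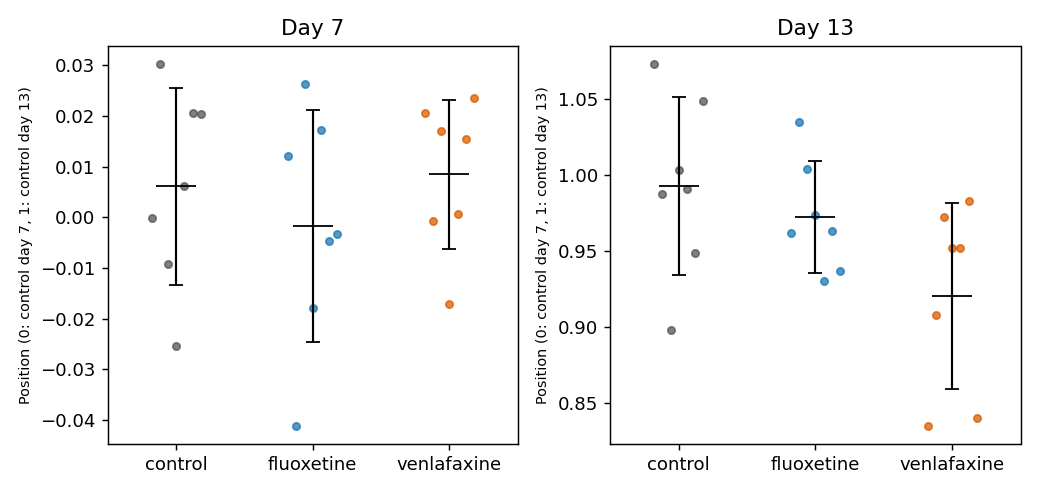
Position of each library on the untreated course (y axis; 0 is the mean of day 7 controls and 1 that of day 13 controls, each control placed with itself left out) for control, fluoxetine and venlafaxine groups on days 7 and 13, with the group mean and SD (n = 7). Venlafaxine on day 13 averaged 0.92 and its controls 0.993.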

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

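Of the tests weighed here, the GC and length correction, the exact test of lists, the permutation of residuals and the fits without the farthest libraries were chosen only after results had been seen. So were the adjustment of the tests of the shared controls over 37 lists, the stem cell mixture, the stem cell level per library and the oligodendrocyte genes as a test of delay, and the share of stem cell genes was set apart from the neuron and cell cycle pattern after its value was known.

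Neuron genes were lower and cell cycle genes higher in venlafaxine than in control cultures on day 13 in camera and in the exact test (adjusted p = 0.0259 for both lists), and neither list held with an estimated correlation (adjusted p = 0.326). Stem cell transcripts were higher beside them, as left-over stem cells would give: of 39 genes abundant on day 0, 94.9% were higher in venlafaxine (bound set at 75%). These genes move together, and in fluoxetine 17.9% were higher though their level per library did not pass a test (unadjusted exact p = 0.735), so the share alone decides little. In venlafaxine the level per library was higher at an unadjusted exact p of 0.0268. The groups overlapped, at 1.85 to 4.15% in venlafaxine and 0.556 to 3.46% in control libraries. Adding the measured excess of 1.25% day 0 RNA to the controls gave a cell cycle median of 0.117 (0.225 with the highest library) where 0.502 was observed. For neuron genes it gave -0.0178 where -0.28 was observed, and for pluripotency genes 0.718 against an observed 0.677. This argues against stem cells in the day 0 state as the source of the neuron and cell cycle changes. The mixture holds the day 0 profile alone, so it cannot decide on undifferentiated cells in a later state. A GC and length trend is argued against by both list tests (2 of 2) kept in camera after its correction, with medians of 0.488 for cell cycle and -0.292 for neuron genes, and a uniform delay along the untreated course by the oligodendrocyte list, which rises with time and was higher, at a median of 0.613. A change in dividing progenitors and glia under the drug may remain, as may a difference between culture batches, which the labels do not name, and neither was tested.

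Lysosome and sterol genes were higher on day 7 with either drug in camera, at 2 and 90 µM. With an estimated correlation the sterol list lost its call for fluoxetine (adjusted p = 0.442, exact adjusted p = 0.313, 0 of 25 genes called) and for venlafaxine (p = 0.0734, exact p = 0.0216), while the lysosome list kept it for both (p = 0.0113 and 7.94e-05). The 7 shared controls lay below the libraries of both drugs pooled in an exact test over all 116280 choices of 7 of the 21 libraries (p = 0.000636 for lysosome and 0.0154 for sterol genes, adjusted over the 37 lists). The test reads the scores that flagged the lists. For lysosome genes, which also passed the exact test in each drug, it argues against chance low controls if the libraries are independent. The tests by drug share these controls, so they are not separate support. For sterol genes in fluoxetine chance is not excluded, since the pooled test can pass through venlafaxine alone. All 4 camera tests (2 lists, 2 drugs) stayed under 0.05 after the GC and length correction, and all 4 exact tests without the farthest libraries, with the closest, sterol genes in fluoxetine, at an unadjusted p of 0.0498. Both drugs are amphiphilic amines, a class known to gather in lysosomes, and a response to this trapping may explain the pattern as a hypothesis. It was not tested, since no compound without this property was included, and a difference in handling between control and treated cultures stays open.

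Hox genes were lower on day 13 with either drug in camera, and lost that call with an estimated correlation (adjusted p = 0.248 for fluoxetine and 0.326 for venlafaxine) and in the exact test (adjusted p = 0.0752 and 0.0583). The controls lay above the libraries of both drugs pooled at an exact p of 0.017 over the choices of 7 of 21 libraries, adjusted over the 37 lists. This test reads the scores that flagged the list and pools the drugs, whose separate exact tests did not pass. Chance high values of the shared controls are therefore not excluded for either drug. A GC and length trend is argued against by 2 of 2 camera tests kept after its correction. A shift from posterior to forebrain identity between cultures could not be settled: within groups, Hox and forebrain scores of 21 libraries had r = -0.241 (permutation p = 0.32; rho = -0.192, permutation p = 0.426) and r = -0.264 without the 2 farthest, the 1 relation computed. An effect of the drugs on posterior patterning may remain, as may chance and a difference in handling of the controls.

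Random splits of the same libraries asked whether chance can be excluded for each count of genes. On day 7, 3 of 80 splits gave as many genes as fluoxetine against control (8 genes; highest other 148), 1 of 80 as venlafaxine against control (599; highest other 282), and 3 of 80 as the 2 drugs against each other (23; highest other 1903). On day 13 these numbers were 2 of 80 for fluoxetine (19; highest other 23), 1 of 80 for venlafaxine (3753; highest other 3174) and 1 of 80 for the drugs against each other (1986; highest other 1). In the time course 1 of 80 gave as many for day 7 against day 0 (15060; highest other 13386) and for day 13 against day 7 (14090; highest other 12215), and 1 of 50 for the day differences of fluoxetine (47; highest other 5) and venlafaxine (2107; highest other 143). Each share, the real split included, was under 0.05, the level set for excluding chance, without adjustment over the comparisons. The counts of 8 and 23 genes, at 3 of 80, lay closest to it, followed by 19 genes at 2 of 80. With other splits calling up to 148, 1903 and 23 genes and no adjustment over the comparisons, chance is not excluded for these. Where the share was 1 of 80 or 1 of 50, the real split alone reached its count. A random split can keep most libraries in their real groups, so the highest other count is not a level given by chance alone. All these shares take the libraries as independent, which the labels do not state. What set apart the splits that called 148 and 1903 genes, several times the real 8 and 23, was not tested.

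A single library stood apart from the other 6 of its group in 7 of 163 groups of values tested, where chance gives 8.15. The 50 most abundant genes took 9.97% of counts in flx_d7_2 (others 9.18 to 9.47%). The oligodendrocyte score was 5.39 in flx_d13_1 (4.83 to 5.07) and the endothelium score 1.64 in flx_d13_5 (2 to 2.24). Rnf145 was at 211 CPM in con_d7_7 (223 to 229), Nkx6-1 at 121 CPM in vnx_d13_5 (77.5 to 92), Hoxb8 at 29.3 CPM in flx_d13_4 (5.56 to 15.6) and Actc1 at 2.06 CPM in vnx_d13_4 (0 to 0.638).

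The effect of fluoxetine differed between day 13 and day 7 (tested as an interaction in edgeR) in 47 genes. As differences of log2 fold changes, Fbln2 was at 1.31, Itih5 at 1.28, Daam2 at 0.64, Ednrb at 0.54, Plekhd1 at -1.09 and Kcnh1 at -0.83. Ednrb alone of these kept its call without the farthest libraries (con_d7_5, con_d13_4, flx_d7_2, flx_d13_5, vnx_d7_5 and vnx_d13_1), and Ednrb and Plekhd1 with no filter. With DESeq2 size factors Fbln2, Itih5 and Kcnh1 lost theirs. In list scores, tested by permutation of residuals, glutamatergic genes differed by -0.335 (adjusted p = 0.0386), astrocyte genes by 0.243, Hox genes by -0.631 and immediate early genes by -0.185 (adjusted p up to 0.0479). Camera called 15 lists for this difference, and 0 with an estimated correlation.

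The effect of venlafaxine differed between the days in 2107 genes. Differences were 2.26 for Clps, 2.04 for Pkd1l1, 0.68 for Plk1, 0.55 for Mki67, 0.96 for the astrocyte gene Ndrg2, 0.78 for Slc2a1, 0.52 for Ldha and 0.91 for Mbp. They were -1.64 for Tlx1, -1.23 for Hoxc5, -0.59 for Hoxb4, -0.49 for Sc5d, -0.52 for Cyp51, -1.16 for En2, -0.62 for Syp, -0.54 for Stmn3, -0.63 for Neurod4 and -0.61 for Insm1. Tlx1 lost its call with no filter and with voom. In list scores the higher effects on day 13 were 0.589 for cell cycle, 0.849 for oligodendrocyte, 0.353 for astrocyte, 0.587 for microglia, 0.468 for early mesoderm, 0.469 for epithelial, 0.424 for choroid plexus, 1.14 for forebrain, 0.472 for hypoxia, 0.215 for oxidative stress and 0.164 for unfolded protein response genes. The lower ones were -0.344 for neurogenic, -0.301 for general neuron, -0.299 for glutamatergic, -0.162 for sterol and -0.0986 for lysosome genes. These had adjusted permutation p from 0.00037 to 0.0388, while camera called 12 lists, and with an estimated correlation astrocyte genes alone (p = 0.0437).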

How the results depend on the processing

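The GC and length correction, the fits without the farthest libraries and the exact test of lists were chosen after seeing the data. Counting each named gene once per comparison, direction and call held for 239 with a filter of 1 CPM, 228 with DESeq2 and 241 with DESeq2 size factors in edgeR. Fewer held with all 49 libraries (213), with voom (211), with no filter (199, 45 lost their call) and without the farthest libraries (197, 41 lost). In fits of the 2 groups alone, which give no day difference, 198 held and 20 lost their call. Of the list results 191 held with DESeq2 size factors and 178 after the GC and length correction, 61 with an estimated correlation (131 lost their call) and 47 in the exact test (54 gained and 59 lost a call). No count of the 2 time course comparisons moved by over 1.5 times, and all positions on the untreated course held. At the depth, spread and number of libraries measured, 20 to 26 of 50 simulated changes of 1.2-fold were found, with genes drawn independently. Whether depth sets this limit was not tested. What caused the counts to move between settings was not tested.

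For fluoxetine on day 7 (8 genes) the count was 15 after the GC and length correction, 5 without the farthest libraries, 57 with DESeq2, 53 with voom, 14 with the 2 groups alone and 18 with all 49 libraries. For the drugs against each other on day 7 (23) it was 56, 14, 112 and 49 in the first 4 of these, and 8 with the 2 groups. For fluoxetine on day 13 (19) it was 29 with no filter, 45 with a filter of 1 CPM, 36 after the correction, 58 without the farthest libraries, 423 with DESeq2, 454 with voom and 575 with all 49 libraries. For venlafaxine on day 13 (3753) it was 2022 with no filter and 2301 with the 2 groups. For the drugs against each other on day 13 (1986) it was 889 with no filter, 236 without the farthest libraries and 3467 with all 49. For the day difference of fluoxetine (47) it was 5 with DESeq2 size factors, 4 with no filter, 5 without the farthest libraries, 181 with DESeq2, 464 with voom and 83 with all 49 libraries. For that of venlafaxine (2107) it was 1186 with no filter.

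The replicate numbers of the labels did not pair the libraries. Libraries of different groups with the same number had a mean correlation of deviations of -0.018 (129 pairs, -0.464 to 0.242) against 0.00256 for different numbers, and 5 of 49 correlated best with their own number. With the number as a block the count was 290 for venlafaxine on day 7 (599), 8 for the drugs against each other on day 7, 0 for fluoxetine and 282 for venlafaxine on day 13, 176 for the drugs against each other on day 13 and 10 for the day difference of fluoxetine. None of the 19 genes called for fluoxetine on day 13 kept its call. Counted once per comparison, 138 named genes held with the block, the fewest of these settings, and 105 lost their call, 46 of them for venlafaxine and 19 for the drugs against each other on day 13.

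Values that changed sign were Slc6a4 for venlafaxine on day 7 (not called, -0.0542 without the farthest libraries and -0.0924 with voom), and several lists. In the exact test these were neural progenitor genes for fluoxetine on day 13 (-0.0348), sterol genes between the drugs on day 13 (-0.0185), microglia genes from day 0 to day 7 (0.886), and early mesoderm (0.258) and immediate early genes (0.186) from day 7 to day 13. From day 0 to day 7 they were hypoxia genes with the block (0.221) and mitochondrially encoded genes after the GC and length correction (0.111). In the day difference of fluoxetine they were pluripotency genes without the farthest libraries (0.0472). The exact test reads the mean of a list's members, where camera sets them against all other genes, so that signs can differ by construction.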

Other observations

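Some members of the endothelial, interferon and other smaller lists were called for venlafaxine on day 13, where 22.9% of all genes were. Of 9 endothelial genes 3 were higher than in control (median log2 fold change 0.41; camera p = 0.012, exact p = 0.0172, p = 0.326 with an estimated correlation). Of 10 interferon genes 4 were higher and 1 lower (median 0.57; camera p = 0.0956, exact p = 0.0215). Of 3 microglia genes counted 1 was higher (median 0.33; camera p = 0.0809, exact p = 0.0144), and of 8 xenobiotic metabolism genes 2 (median 0.26; camera p = 0.168, exact p = 0.0255). Neural crest genes went both ways, with 4 higher and 2 lower, and 1 p53 target was higher and 2 were lower. Of 13 heart and skeletal muscle genes 0 were called in fluoxetine against control on day 13 (median 0.90; camera p = 0.0341, p = 0.513 with an estimated correlation, exact p = 0.486). Against venlafaxine 4 were higher in fluoxetine (median 0.51; camera p = 0.175, exact p = 0.205).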
